A study of Homo sapiens with 4 samples.

How the data were processed

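RNA was measured in 4 libraries of the A375 melanoma line, 1 per group: vector, overexpression, scramble and knockdown. Per the labels, total RNA was extracted with TRIzol, poly(A) RNA was enriched on beads, and libraries were made with a whole-transcriptome kit for Ion Torrent sequencing. The submitters' processing notes name TopHat2 2.0.13, Bowtie2 2.2.4, SAMtools 1.1, Cufflinks 2.2.0 and the hg19 build, without the role or order of each tool. The gene annotation, the read counts and any filter are not given in the sources used here. The extraction text of the labels speaks of 2 samples, and whether both pairs were prepared together is not stated there, so the difference between the controls, and any comparison across pairs, may also hold a difference in preparation. The deposited values are RPKM, scaled to transcript length and library size, per the file headers, with 1 value for each of 23284 gene symbols in every library. No symbol was repeated, and 91 rows joined several symbols, as for MAGEA2 and MAGEA2B. Of 34 genes used by every cell, 0 were listed at 0 in any library. The ribosomal protein gene RPL21, outside that list, was yet at 0.019, 0.028 and 0.0155 RPKM in the vector, overexpression and scramble libraries. A listed 0 elsewhere may thus also be a failed estimate.

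Groups came from the sample titles. The overexpression library was compared with the vector library and the knockdown library with the scramble library, as the labels name them as controls, and the scramble library was set against the vector library as a measure of how far libraries without a MAGE-A1 construct differ. For each gene at 1 RPKM or more in either library of a pair, log2((RPKM + 1)/(RPKM + 1)) was computed, with a pseudocount of 1. Genes at or past a log2 ratio of 1 in size (2-fold) were counted in each direction. With 1 library per group there was no test, and the differences compare libraries, not conditions. Genes past 2-fold in both pairs were counted beside n1 × n2 / N, the overlap of independent lists. Correlations across genes carry no p-value, since genes are not replicates.

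A set of 33 gene lists was fixed before the data were examined, as were the comparisons, the filter, the threshold and all alternatives but the trend removal. They cover the genes of the series title, MAGE-A and other cancer-testis genes, AP-1 factors, inflammatory genes, MAPK output, cell cycle phases, p53, melanocyte, invasive state, adhesion, proteases, matrix, interferon, stress, heat shock, cholesterol, hypoxia, Notch, TGF-beta, ribosomal proteins, oxidative phosphorylation, histones, structural small RNAs, long genes, genes used by every cell, and fibroblast, keratinocyte, leukocyte, endothelial and neuronal markers. Each list's median log2 ratio was placed as a percentile among 10000 random lists of equal size, matched in 20 bins of mean expression. A list with at least 5 measured members was said to stand apart below percentile 2.5 or above 97.5. This describes these libraries. Of the lists, 1 is not reported here, nor are some single genes. Lists overlap in places: LIF, IL6, MAFF and FOSL1, for instance, belong to more than 1 list.

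Genes named were set by a rule made at the same time. It took MAGEA1 and the genes of the title. In each main pair it took the 8 highest and 8 lowest genes among those at 5 RPKM or more in either library and past 2-fold the same way against the other control too. It took the 5 leading genes in each mirrored direction, the 5 highest and 5 lowest between the controls, and up to 4 members with the largest ratios of each list that stood apart or had 3 or more members past 2-fold. Small RNA genes and symbols starting with LOC were left out of all but the list part, 366 of those that met the criteria in each main pair. Small RNA genes were recognized by the start of their symbol. The SNAR noncoding RNAs and TERC were not covered by that rule, so they count with the other genes throughout. Any other gene named, such as MAGE-A paralogs and marker genes of other cell types, was chosen after its values were seen.

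The deposited RPKM hold no counts, so depth was estimated from the steps in low values. For 4128 genes of over 600 nt with a single GENCODE 29 transcript, RPKM × (length - 200)/1000 fell in whole multiples of the value of 1 read, where 200 nt was the shift that sharpened the steps most. Among values of about 1 to 5 reads, 61.2% to 65.2% lay within 0.1 of a whole read, against 20% by chance. The estimates were 24630000, 12660000, 16410000 and 19630000 reads in the vector, overexpression, scramble and knockdown libraries, so that 1 RPKM in a transcript of 2000 nt stands for 44.3, 22.8, 29.5 and 35.3 reads. Reads of MAGEA1, JUN, IL8 and ARHGAP29 were estimated in this way, and the ratios have exact conditional (Clopper-Pearson) 95% intervals. They cover counting error only, and they take the transcript length as that of the longest GENCODE transcript.

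Transcript length and GC content came from the longest transcript of each gene in GENCODE 29, matched by symbol or RefSeq synonym for 92.2% of symbols and for 95.2% of the measured genes without small RNA in both main pairs. Coordinates printed are those of GENCODE 29 on GRCh38, and hg19 coordinates were not used. A trend was removed, where stated, by a Huber fit of the log2 ratio on cubic terms of log2 length and GC content over genes other than small RNA genes. This alternative was chosen after seeing the data.

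The steps were tested on simulated libraries made from the vector library for the overexpression comparison. The simulation held counting error alone, with the same 200 nt shift and independent genes. Its error rates thus do not cover other differences between real libraries. Between the controls, 122 of 12957 genes other than small RNA genes were past 2-fold. All of the 34, 34, 33, 33, 33 and 33 genes changed by log2 1.5, 2, 3, -1.5, -2 and -3 were past 2-fold, as was 1 of 11883 unchanged genes. Estimated depth was off by 0.0%, 96.8% of intervals held the true ratio, and 6.0% of 200 unchanged lists and 100% of 200 lists shifted by 0.5 stood apart. An added length trend with rho of -0.938 was at -0.001 after removal. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

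The alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5, upper quartile and median ratio rescaling, the other control library, the mean of both controls, small RNA genes left out, a 4-fold threshold for counts, and the trend removal. RPKM is relative to the library total, so a class that takes a larger share of reads lowers the values of all other genes. Short genes get large values from few reads, so a share of summed RPKM is not a share of reads.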

Results

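The series measured RNA in A375, a human melanoma cell line with an activating BRAF mutation. MAGE-A1 belongs to the cancer-testis antigens, proteins made in testis and in many tumours but in few other adult tissues. Of the 4 libraries, 1 came from cells stably carrying the empty pcDNA3 vector (vector library) and 1 from cells with MAGE-A1 cloned into that vector (overexpression library). Another came from cells carrying a pRNAT plasmid with a scrambled hairpin (scramble library) and the last from cells with a hairpin against MAGE-A1 (knockdown library). Poly(A) RNA was sequenced on an Ion Torrent instrument. Each group held 1 library, so no difference below has a replicate check, no test was run and no p-value is given. Read depth, estimated from the steps in the low values, was 24630000 reads in the vector library, 12660000 in the overexpression library, 16410000 in the scramble library and 19630000 in the knockdown library. Levels are RPKM, and ratios are log2 of (RPKM + 1) in a library over (RPKM + 1) in its own control, which understates the ratio of low genes. Higher and lower mean at least 2-fold (log2 of 1) unless a value is given.

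MAGEA1, the targeted gene (GRCh38 chromosome X, 153179285 to 153183880, plus strand), was at 1.80 RPKM in the vector library and 126 in the overexpression library, a log2 ratio of 5.50. It was at 0.767 in the scramble library and 0.473 in the knockdown library, a log2 ratio of -0.26. The estimated reads on the gene were 67 in the vector, 2406 in the overexpression, 19 in the scramble and 14 in the knockdown library. From these reads the ratio of overexpression to vector was 69.9 (95% exact conditional interval 54.8 to 90.4), and that of knockdown to scramble was 0.616 (0.286 to 1.30). The interval of the knockdown ratio includes 1, so a MAGEA1 level lower than in its own control was not detectable at this depth. Against the vector library the knockdown library was at 0.262 (0.136 to 0.471) and the scramble library itself at 0.426 (0.242 to 0.717). These intervals cover counting error alone. Of the MAGE-A family list, 10 members could be measured with overexpression, and 2 were higher, MAGEA1 and MAGEA10 (24.1 to 50.1 RPKM). With knockdown 8 could be measured and 1 was lower, MAGEA10 (27.2 to 12.6 RPKM). MAGEA10 passed narrowly (1.02 and -1.06), and neither call held with the controls exchanged (0.85 and -0.89) or with a fitted length and GC trend removed (0.96 and -0.99). The abundant paralogs stayed within 2-fold: MAGEA4 was at 621, 507, 560 and 371 RPKM in the vector, overexpression, scramble and knockdown libraries, and MAGEA3 at 107, 128, 98.9 and 91.8. MAGE-A genes are near-identical in places, so the split of reads among them is uncertain, and the paralogs named were picked after their values were seen. The family median was 0.26 with overexpression (percentile 65.6 among matched random lists) and -0.23 with knockdown (percentile 2.69). The knockdown median of the family with the trend removed was -0.49 at percentile 0.31, where it stood apart, as did the family between the controls (-0.20, percentile 0.70). It also stood apart with no filter (percentile 0.76) and against the vector library (-0.43, percentile 1.58).

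The series title places c-JUN, IL8 and ARHGAP29 in a network affected by MAGE-A1, and all 3 were higher with overexpression and lower with knockdown. JUN, an AP-1 transcription factor, was at 11.03 RPKM in the vector and 42.0 in the overexpression library, and at 15.4 in the scramble and 1.73 in the knockdown library, log2 ratios of 1.84 and -2.59. IL8 (CXCL8), a neutrophil-attracting chemokine, was at 42.5 and 133 in the first pair and at 62.5 and 5.75 in the second, log2 ratios of 1.62 and -3.23. ARHGAP29 was at 6.84 and 20.1 in the first pair and at 11.9 and 0.793 in the second, log2 ratios of 1.43 and -2.85. From reads, the ratios of overexpression to vector were 3.81 for JUN (95% interval 3.51 to 4.13), 3.12 for IL8 (2.93 to 3.33) and 2.94 for ARHGAP29 (2.71 to 3.18). The ratios of knockdown to scramble were 0.112 for JUN (0.0910 to 0.136), 0.0921 for IL8 (0.0781 to 0.108) and 0.0667 for ARHGAP29 (0.0534 to 0.0826). The study chose these genes, so their direction here is not independent evidence. Each was also higher in the scramble than in the vector library, by log2 ratios of 0.45, 0.54 and 0.72, and against the scramble library ARHGAP29 with overexpression stood at 0.70, under 2-fold. In GRCh38, JUN lies on chromosome 1 at 58780788 to 58784327 (minus strand), CXCL8 on chromosome 4 at 73740506 to 73743716 (plus strand) and ARHGAP29 on chromosome 1 at 94148988 to 94275068 (minus strand).

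**Figure D1:**
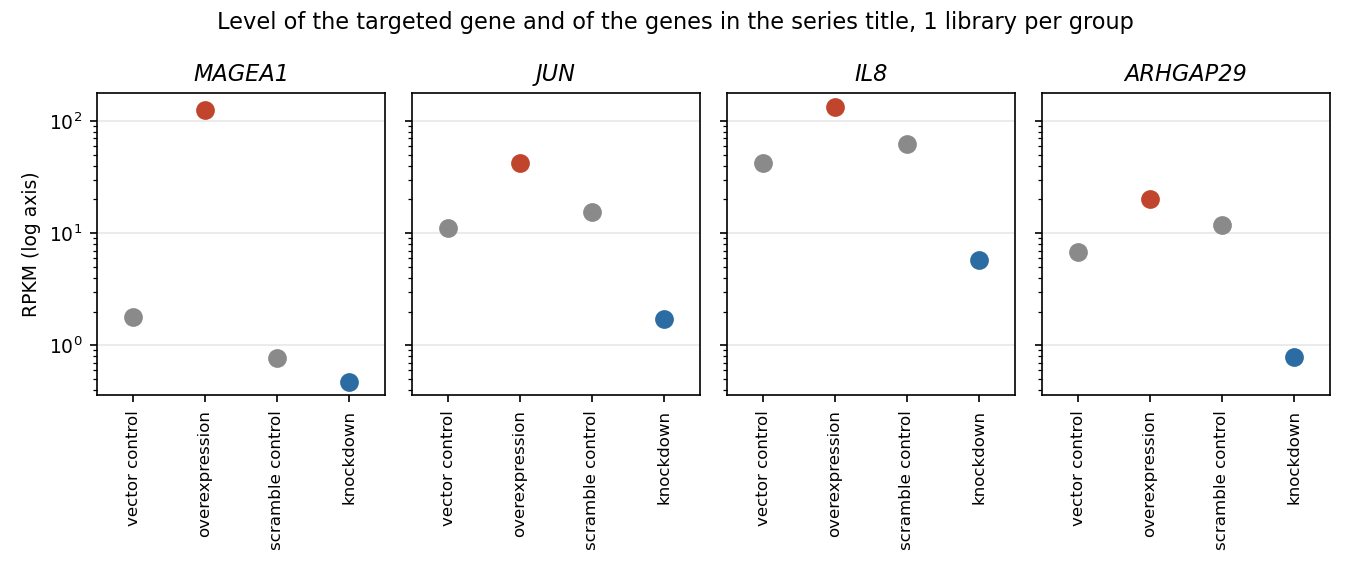
RPKM (log axis) of MAGEA1, JUN, IL8 and ARHGAP29 in each library, with 1 point per library and no error bar because each group has 1 library. JUN, IL8 and ARHGAP29 are highest in the overexpression library (42.0, 133 and 20.1 RPKM) and lowest in the knockdown library (1.73, 5.75 and 0.793 RPKM).

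With MAGE-A1 overexpression, the lists of inflammatory cytokines, AP-1 factors and the response to unfolded protein and amino acid shortage had median log2 ratios of 1.67, 1.52 and 1.73. Those of S phase, of mitosis and of heat shock genes had medians of -0.63, -0.66 and -0.80, with most members within 2-fold. IL24, a cytokine of the IL10 family, was at 28.9 RPKM in the vector and 1622 in the overexpression library (log2 ratio 5.76). IL11, a cytokine of the IL6 family, reached 352 RPKM with overexpression (5.55), and ESM1, a proteoglycan secreted by endothelial and tumour cells, at 1.28 and 115 (5.66). Against its own control, 1439 of 13577 genes were higher and 988 lower. Between the scramble and vector libraries, which differ in plasmid and culture but carry no MAGE-A1 construct, 119 of 13326 were higher and 238 lower.

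Among inflammatory chemokines and cytokines, 15 of 23 measured members were higher and 1 lower (median log2 ratio 1.67, percentile 100 among random lists). Besides IL24 and IL11, CSF2 went from 0.0696 to 18.1 RPKM and IL6 from 0.165 to 16.6. Of the AP-1 factors, 9 of 13 were higher and 0 lower (median 1.52, percentile 100), with ATF3 at 5.41 and 104 RPKM, MAFF at 6.44 and 44.1, and FOSL1 at 109 and 532. Of the genes that report MAPK pathway output, 11 of 22 were higher and 0 lower (median 1.00, percentile 99.98), with EGR1 at 22.7 and 276 RPKM, the phosphatase DUSP5 at 12.1 and 119, and LIF at 20.2 and 175. The unfolded protein response and amino acid stress list had the highest median among lists of protein-coding genes, 1.73, with 17 of 24 higher and 0 lower. CHAC1, which degrades glutathione, was at 2.06 and 95.1 RPKM, the transcription factor DDIT3 (CHOP) at 32.0 and 622, and PPP1R15A, a phosphatase subunit acting on eIF2 alpha, at 30.9 and 465.

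Of the S phase genes, 6 of 27 were lower and 0 higher with overexpression (median -0.63, percentile 0.0), with E2F1 at 20.5 and 6.98 RPKM and MCM5 at 40.6 and 15.3. Of the G2 and mitosis genes, 9 of 28 were lower and 0 higher (median -0.66, percentile 0.0), with the kinesin KIF20A at 44.1 and 4.95 and MKI67 at 88.3 and 30.1. Heat shock genes had 6 of 15 lower and 0 higher (median -0.80), led by HSPA8 at 920 and 140 RPKM. Hypoxia and glycolysis genes had a median of -0.46 (percentile 0.01), while 3 of 28 were higher, among them VEGFA at 12.7 and 72.2 RPKM and ADM at 11.9 and 38.0 (0.63 against the scramble library, under 2-fold), and 4 were lower, among them CA9 at 4.71 and 0.175. Oxidative phosphorylation genes had 0 of 40 past 2-fold and a median of -0.18 (percentile 0.13). Cholesterol synthesis genes had a median of -0.35 (percentile 0.88), with NSDHL, a sterol dehydrogenase, at 16.2 and 6.64 RPKM. With a length and GC trend removed the cholesterol median was -0.22 at percentile 4.12 and the list no longer stood apart. Genes used by every cell had 7 of 34 lower and 1 higher (median -0.31, percentile 0.0), with tubulin TUBB at 687 and 236 RPKM and the ferritin gene FTH1 at 114 and 633.

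Other lists with members past 2-fold did not stand apart with overexpression. In the invasive dedifferentiated melanoma list, 11 of 25 were higher and 2 lower (median 0.33, percentile 90.04), with the receptor AXL at 53.8 and 347 RPKM. Among genes at 5 RPKM or more its median was 0.95 and it stood apart (percentile 99.98). The p53 target list had 6 of 23 higher and 5 lower (median -0.12, percentile 10.5), with GDF15 at 5.89 and 161 and the kinase PLK2 at 70.2 and 17.3. The matrix protease list had 5 of 23 higher and 3 lower (median 0.45, percentile 97.45, just under the bound), and it stood apart without small RNA genes (percentile 99.3) and with the trend removed (percentile 99.9). The interferon list had 2 of 28 higher and 7 lower (median -0.18, percentile 13; IFIT1 7.29 and 0.666), but stood apart against the scramble library (-0.37, percentile 1.68) and against the mean of both controls (-0.38, percentile 1.26). The TGF-beta and BMP list had 2 of 14 higher and 6 lower (median 0.00, percentile 43.6). Cadherins and integrins (median -0.01, percentile 19.5), collagens and matrix (-0.06, 15.8), Notch targets (0.01, 53.9), melanocyte lineage genes (0.03, 46.4), ribosomal proteins (0.07, 5.73; -0.01 and 2.44, thus apart, against the mean of both controls) and long genes (0.26, 77.5) did not stand apart either. Other cancer-testis antigens (-0.44) lay at percentile 2.58, just inside the bound, and stood apart without small RNA genes (percentile 2.44) and with the trend removed (percentile 1.12).

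The lowest genes with overexpression included ASB9, a subunit of ubiquitin ligases (22.3 to 1.00 RPKM, log2 ratio -3.54), IGFBP5, which binds insulin-like growth factors (91.2 to 7.07, -3.51), and HAPLN1, a hyaluronan-binding matrix protein (63.6 to 5.27, -3.37). LZTS1 (-3.27), the homeobox gene MEOX2 (-3.20), the neuronal tubulin TUBB3 (-3.01) and the protocadherin PCDH7 (14.4 to 0.923 RPKM) followed. WBP1 was at 19.2 RPKM in the vector library and listed at 0 with overexpression. The retroposon-derived TRIML2 was at 1.77 and 115 RPKM and the histone gene HIST1H4D at 1.23 and 75.9. SNAR-A4 and SNAR-A14, members of a multicopy noncoding RNA family, were each at 31.4 with overexpression and listed at 0 in both controls, and reads among such copies are uncertain.

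Of 442 small RNA genes measured with overexpression, 334 were higher and 67 lower. MicroRNA genes went both ways, with 58 of 148 higher and 58 lower (median 0.89), and the higher ones were mostly snoRNA genes, whose transcripts carry no poly(A) tail. Small RNA genes made up 87.2% of the summed RPKM in the overexpression library and 46.3% in the vector library. These are not shares of reads, since very short genes get large RPKM from few reads. The summed RPKM of other genes was 417427 in the overexpression and 375609 in the vector library, thus not lower. Their median was lower, at 2.52 against 2.81, and their upper quartile was 15.5 against 14.6. Of the C/D box snoRNA genes, 157 of 165 were higher (median log2 ratio 4.18), and of the H/ACA box genes 90 of 94 (3.73). All 12 measured structural small RNAs were higher (median 2.60; RNU12 19.2 and 1181 RPKM). Of the replication-dependent histones, whose RNA also lacks the tail, 18 of 28 were higher and 1 lower (median 1.45, percentile 100), with HIST2H2AC at 4.14 and 47.7, and histone genes share sequence, so single values are uncertain. Without small RNA genes, 1105 of 13135 genes were higher and 921 lower. With each library rescaled to a common upper quartile, which moved the median of all genes by -0.16, 1168 were higher and 1402 lower.

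With MAGE-A1 knockdown, the lists of the invasive melanoma state, of matrix genes and of cadherins and integrins had median log2 ratios of -1.19, -0.86 and -0.39, and those of cholesterol synthesis and oxidative phosphorylation had medians of 0.78 and 0.98. ITGB4, the integrin beta 4 subunit, was at 62.9 RPKM in the scramble and 0.954 in the knockdown library (log2 ratio -5.03), the hair keratin KRT81 at 60.6 and 0.566 (-5.30) and C19orf33 at 43.1 and 0.205 (-5.19). Against the scramble library, 1688 of 13569 genes were higher and 1156 lower. Rescaling to a common upper quartile moved the median of all genes by -0.26, and then 1029 were higher and 1969 lower.

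Of the invasive dedifferentiated melanoma list, 13 of 24 were lower and 0 higher with knockdown (median -1.19, percentile 0.0). THBS1, a matricellular protein, was at 294 and 33.3 RPKM, CAV1, the caveolin of membrane pits, at 97.1 and 18.6, CTGF at 50.4 and 9.41, and AXL at 80.6 and 21.9. Of the collagens, laminins and matrix genes, 11 of 22 were lower and 0 higher (median -0.86, percentile 0.0), with COL12A1 at 20.8 and 1.68 and FN1 at 52.2 and 11.9. Of the cadherins, integrins and EMT genes, 9 of 25 were lower and 3 higher (median -0.39, percentile 0.09), with L1CAM at 134 and 15.02, ITGB8 at 30.4 and 3.40, and ITGAV at 27.3 and 4.95. Matrix proteases had 5 of 21 lower and 3 higher (median -0.15, percentile 1.14), with MMP16 at 39.4 and 10.4, TIMP1, a protease inhibitor, at 164 and 682, and MMP1 at 0.358 and 5.36.

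Transcript length went with these ratios in the knockdown pair. Across the 12514 genes with a known length and no small RNA, Spearman's rho of the knockdown log2 ratio with transcript length was -0.521 and with GC content 0.428, and genes are not independent replicates. Genes of up to 500 nt had a median log2 ratio of 0.97 and those above 8000 nt one of -0.60. In the overexpression pair rho with length was 0.056 and with GC -0.216, and between the controls -0.167 and 0.520. A list of long genes had 12 of 20 lower and 1 higher with knockdown (median -1.14, percentile 0.0), with FAT1 at 34.8 and 8.31 RPKM and MACF1 at 52.8 and 16.7, while the long nuclear RNA MALAT1 was at 425 and 2019. With the trend removed 4 of these 20 were lower and 2 higher, with a median of -0.55 (percentile 0.0). With small RNA genes left out, 1330 of 13150 genes were higher and 1120 lower. With a fitted length and GC trend removed as well, over the 12514 genes with a length, 701 were higher and 589 lower. On that scale the invasive list had a median of -0.73 (percentile 0.0), matrix genes -0.74 (0.0), cadherins and integrins -0.46 (0.0) and matrix proteases -0.38 (0.03), all still apart from random lists. The list of long genes, at -0.55, was still apart as well. A length effect that the fit left in place can therefore not be told apart in these lists. The lower members were then 11 of 24 in the invasive list, where 1 was higher, and 10 of 22 matrix genes. They were 5 of 25 cadherins and integrins, where 3 were higher, and 3 of 21 matrix proteases, where 3 were higher too.

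**Figure D2:**
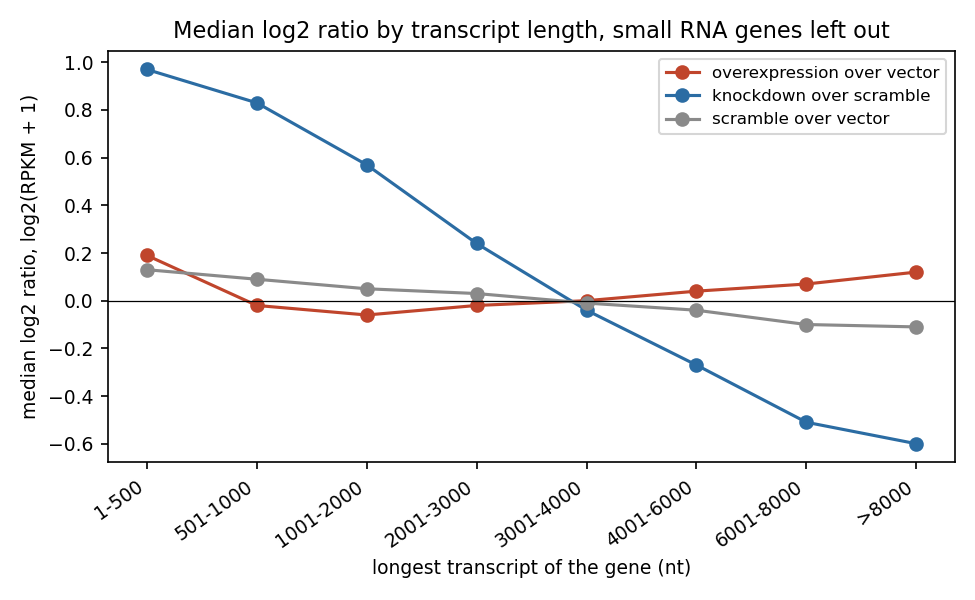
Median log2 ratio of genes in 8 bins of transcript length (nt, longest transcript), small RNA genes left out, with 1 line per comparison. The knockdown line goes from 0.97 in the shortest bin to -0.60 in the longest, while the overexpression line lies between -0.06 and 0.19 and the line between the controls between -0.11 and 0.13.

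Of the cholesterol synthesis genes, 8 of 21 were higher and 0 lower with knockdown (median 0.78, percentile 99.7; 0.74 and percentile 100 with the trend removed, where 7 were higher), with MVD at 9.59 and 42.2 RPKM, EBP at 38.6 and 146, and DHCR7 at 33.8 and 110. Oxidative phosphorylation genes had 19 of 40 higher and 0 lower (median 0.98, percentile 99.3; 0.48 and 99.7 with the trend removed, where 5 of 40 were higher; 0.89 and percentile 85.4, no longer apart, against the vector library), with ATP5G1 at 154 and 464. Large-subunit ribosomal proteins had 20 of 44 higher and 0 lower (median 0.94) at percentile 77.3, with RPLP2 at 797 and 3323. Without small RNA genes that median lay at percentile 99.4 and the list stood apart. With the trend removed 10 of 44 were higher and the median was 0.49 at percentile 99.7. RPL21 was at 0.0155 and 55.7 RPKM, and its many processed copies make that value uncertain. G2 and mitosis genes had 4 of 28 lower and 1 higher (median -0.32, percentile 0.01), with the scaffold ANLN at 66.6 and 16.1 and CDK1 at 49.9 and 22.7, and PTTG1 higher at 75.7 and 174. S phase genes had 1 of 27 lower, CCNE2 at 7.27 and 1.964, and 0 higher (median -0.11, percentile 1.13), and against the vector library their median was 0.09. Heat shock genes had 3 of 15 higher and 0 lower, among them HSPB1 at 193 and 440 RPKM and HSP90AA1 at 403 and 818. Their median of 0.14 lay at percentile 2.48, and it was -0.14 after upper quartile rescaling and at percentile 26.8 with the trend removed, where 1 was higher, and at percentile 4.58 without small RNA genes. Hypoxia and glycolysis genes had 2 of 28 lower, HK2 and SLC2A1, and 0 higher (median -0.11, percentile 0.21), and the median was 0.27 against the vector library and at percentile 3.55 with the trend removed. Genes used by every cell had 5 of 34 higher and 0 lower (median 0.53, percentile 1.17; percentile 23.9 with the trend removed, where 3 were higher and 1 lower, and 11.5 without small RNA genes), with FTH1 at 184 and 1692 and FTL at 916 and 3151.

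Several lists held members past 2-fold with knockdown but did not stand apart, though some did in other settings. The AP-1 list had 3 of 13 lower and 0 higher, JUN, FOSL2 at 17.4 and 6.93 RPKM and FOS at 43.2 and 18.1, with a median of 0.39 (percentile 86.3). With the trend removed that median was -0.36 (percentile 1.33) and 2 of 13 were lower, with FOSL2 at -0.90, and against the vector library FOSL2 was at -0.17. Inflammatory genes had 6 of 18 lower and 2 higher (median -0.26, percentile 8.65; -0.30 and percentile 1.81 with the trend removed), with IL1B at 13.9 and 0.432, CXCL1 at 63.9 and 7.52, and IL24 at 23.2 and 289. The unfolded protein response and amino acid stress list had 7 of 24 higher and 0 lower (median 0.56, percentile 82.2; 0.47 and percentile 99.5 with the trend removed, where 4 were higher and 1 lower), with CHAC1 at 3.24 and 34.5, TRIB3 at 20.9 and 112, and DDIT3 at 34.2 and 169. MAPK output genes had 2 of 22 higher and 4 lower (median 0.01, percentile 3.15), p53 targets 4 of 23 higher and 1 lower (0.05, 28.2; GDF15 5.79 and 81.5 RPKM), and Notch targets 2 of 10 higher and 3 lower (-0.24, 28.8; NOTCH2 56.2 and 11.1). Other cancer-testis antigens had 6 of 15 higher and 1 lower (0.59, 95.8; PAGE5 159 and 469), interferon genes 4 of 29 higher and 3 lower (-0.09, 31.4), TGF-beta and BMP targets 3 of 14 higher and 1 lower (0.19, 60.0), and melanocyte lineage genes 0 of 12 higher and 1 lower (-0.03, 25.8). Cancer-testis antigens stood apart with a pseudocount of 5 (percentile 98.8), no filter (99.95), the vector library as control (98.7) and the mean of both controls (97.53). Among genes at 5 RPKM or more, Notch targets (-1.69, percentile 0.0), MAPK output (0.01, 2.21) and melanocyte genes (-0.39, 2.48) stood apart. With the trend removed 3 cancer-testis antigens, 1 p53 target and 0 interferon genes were higher. Of single genes named for the knockdown pair, HSPB1 (0.12), EGFL7 (0.27, an endothelial marker given below), PTTG1 (0.62), ATP5G1 (0.69), PAGE5 (0.84), HK2 (-0.92), FTL (0.94) and MMP16 (-0.99) were then under 2-fold. SLC2A1 (-0.66) was under 2-fold against the vector library.

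**Figure D3:**
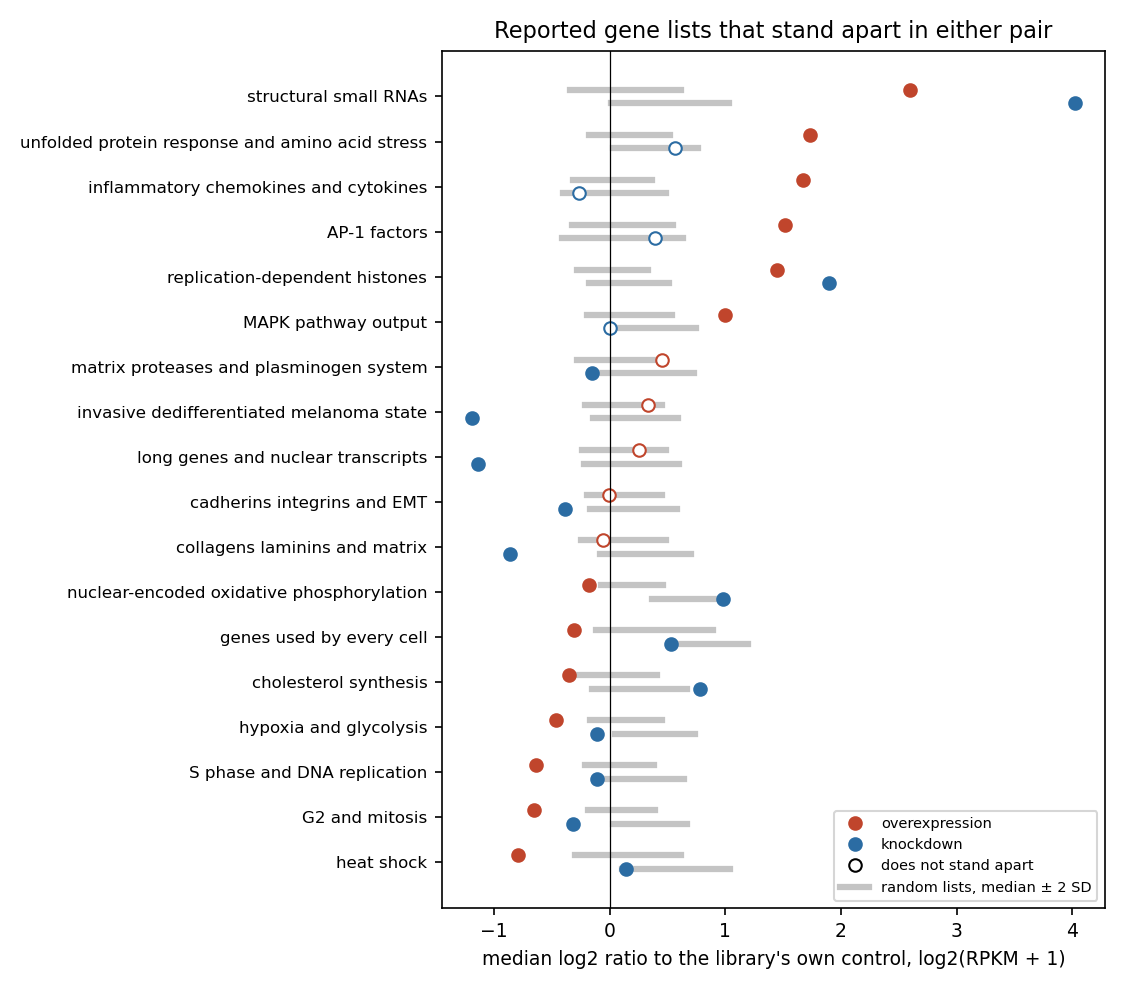
Median log2 ratio to the library's own control, on log2(RPKM + 1), of the reported fixed lists that stood apart from matched random lists in either pair, with overexpression in red and knockdown in blue. Filled points stood apart, open points did not, and grey bars span 2 SD of the random-list medians on each side of their median. The stress list lies at 1.73 with overexpression and 0.56 with knockdown, and the invasive list at 0.33 and -1.19.

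Further genes at the low end of the knockdown pair were KRT80 (61.6 to 3.34 RPKM, log2 ratio -3.85), the semaphorin SEMA3C (40.9 to 2.09, -3.76), the intestinal protease TMPRSS15 (10.2 to 0.0136, -3.47) and CRIM1, which binds BMPs (77.1 to 6.23, -3.43). ANKRD30BL was at 33.9 in the scramble library and listed at 0 with knockdown. At the high end were members of the SNAR family (SNAR-A4, SNAR-A2, SNAR-A10 and SNAR-A12, 60.1, 58.4, 50.1 and 19.5 RPKM with knockdown and listed at 0 in the scramble library), HIST1H4D (3.32 to 83.7), PPP1R27 (0.918 to 34.3) and TERC, the telomerase RNA (0.734 to 26.1). Of 419 small RNA genes, 358 were higher with knockdown and 36 lower, and of 126 microRNA genes 69 were higher and 36 lower (median 1.65). Small RNA genes made up 78.1% of the summed RPKM with knockdown and 29.5% in the scramble library, again not shares of reads. The summed RPKM of other genes was 390378 in the scramble library and 555580 with knockdown. Their median was 2.78 and 2.24, and their upper quartile 14.2 and 14.3. Here 160 of 163 C/D box snoRNA genes were higher (median 5.67), 94 of 94 H/ACA box genes (5.44), 12 of 12 structural small RNAs (4.02; RNU12 51.9 and 4541 RPKM) and 23 of 28 histone genes (1.90; HIST2H2AC 4.41 and 81.4). With the trend removed 15 of 28 histone genes were higher, with a median of 1.09. VTRNA1-1 was at 345 with knockdown and listed at 0 in the scramble library. Without small RNA genes, 1330 of 13150 genes were higher and 1120 lower.

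If both designs acted on the same genes in opposite directions, genes higher with overexpression would be lower with knockdown. Among genes at 5 RPKM or more in a library of each pair, those with the largest smaller ratio of both were TXNIP, an inhibitor of thioredoxin (27.2 to 191 RPKM with overexpression and 25.4 to 1.46 with knockdown), KRT80 (32.0 to 150 and 61.6 to 3.34), the cell adhesion gene NTM (4.08 to 21.6 and 8.27 to 1.14), FAM129A (19.5 to 89.4 and 23.6 to 5.48) and C19orf21 (1.85 to 11.3 and 5.70 to 0.691). In the opposite sense stood MGP, a calcification inhibitor (9.56 to 2.77 and 9.52 to 79.4), BSCL2, the lipid droplet protein seipin (29.1 to 4.71 and 36.8 to 132), SSX2 (8.64 to 1.27 and 2.17 to 9.35), the nuclease ENDOG (16.4 to 3.08 and 11.1 to 32.8) and the vesicle GTPase RAB3A (7.05 to 0.486 and 7.68 to 22.6). With the control libraries exchanged, TXNIP, KRT80, NTM, FAM129A, MGP, BSCL2 and RAB3A stayed past 2-fold in both pairs, ENDOG stood at 0.96 with knockdown, and C19orf21 (0.88 and -0.75) and SSX2 (-0.48 and 0.10) did not pass in either. With the length and GC trend removed, RAB3A stood at 0.76 and ENDOG at 0.44 with knockdown.

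Among 13106 genes measured in both pairs, 127 were higher with overexpression and lower with knockdown, where independent lists would share 113.7, and 63 were lower and then higher, where 110.3 would be shared. In the same direction, 475 were higher in both (156.6 if independent) and 130 lower in both (80.1). Without small RNA genes the mirrored counts were 120 (87.6 if independent) and 55 (87.5), and the counts in the same direction 182 (97.9) and 119 (78.3). With the length and GC trend removed they were 88 (43.6), 25 (40.7), 132 (49.9) and 88 (35.6). Across genes, Pearson's r of both sets of log2 ratios was 0.487 and Spearman's rho 0.083, and without small RNA genes r was 0.076 and rho 0.020. The pairs share no library.

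**Figure D4:**
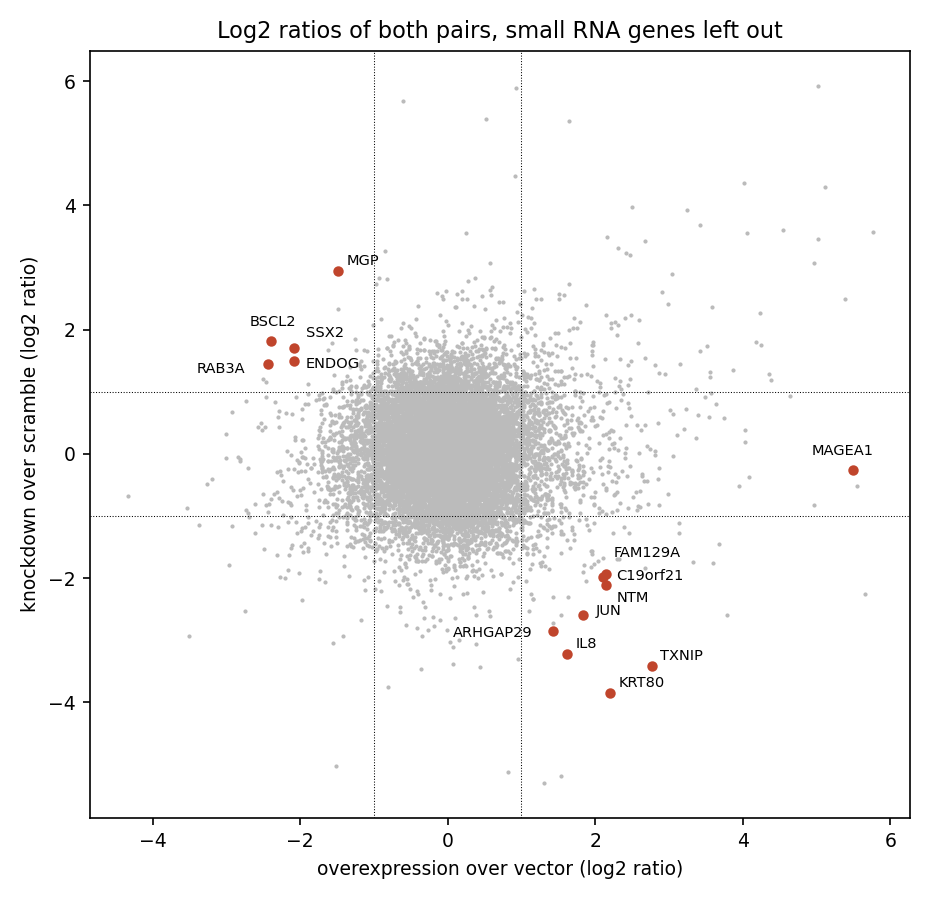
Log2 ratio with overexpression (horizontal) against log2 ratio with knockdown (vertical), each point a gene, small RNA genes left out, dotted lines at 2-fold. The genes of the series title and the leading mirrored genes are marked in red, with JUN at 1.84 and -2.59 and MGP at -1.49 and 2.94.

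Between the control libraries, SEMA3F (5.58 to 19.9 RPKM), C19orf33 (10.9 to 43.1), PLAC8 (2.55 to 10.1) and HIST1H3C (5.05 to 19.2) were higher in the scramble library, and KRTAP22-1 was at 12.1 there and listed at 0 in the vector library. SNAR-C4, SNAR-A10, SNAR-A3, SNAR-A2 and SNAR-D, at 67.1, 24.4, 24.4, 23.7 and 17.3 RPKM in the vector library, were listed at 0 in the scramble library. Of 12957 genes other than small RNA genes, 77 were higher and 45 lower in the scramble library. Of 369 small RNA genes 42 were higher and 193 lower (median -1.20), and of 136 C/D box snoRNA genes 7 were higher and 87 lower (median -1.51). Without small RNA genes, Pearson's r across genes was 0.980, against 0.902 for overexpression with vector, 0.915 for knockdown with scramble and 0.834 for overexpression with knockdown. Between the controls, lists stood apart with medians of 0.24 (AP-1 factors), 0.23 (inflammatory genes), 0.17 (G2 and mitosis), 0.19 (hypoxia and glycolysis), 0.51 (histones), 0.71 (structural small RNAs) and 0.70 (keratinocyte markers, 5 genes, with KRT8 at 27.3 and 59.2 RPKM). With the trend removed the AP-1 median between the controls was 0.06 at percentile 89.1 and no longer stood apart. Lists of S phase (0.17), p53 targets (-0.15), the invasive state (0.18) and cholesterol synthesis (0.14) then did. Before removal the unfolded protein response list had a median of 0.06 (percentile 72.8) and the invasive list of 0.11 (percentile 87.6).

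Most markers of other cell types were too low to pass the filter, and some were not. The leukocyte gene PTPRC was at 0.0436, 0.0170, 0 and 0.0109 RPKM in the vector, overexpression, scramble and knockdown libraries, the endothelial gene PECAM1 at 0.0382, 0.0557, 0.1002 and 0.108, the fibroblast collagen COL1A2 at 0.117, 0.0151, 0.0818 and 0.312, and the epithelial gene EPCAM at 0.0802, 0, 0.0803 and 0.134. These genes, and KRT8 above, were picked from their lists after their values were seen. With overexpression the fibroblast list had 3 measured members (median -0.60), leukocyte markers 2 (-0.80), endothelial markers 4 (-0.07) and neuronal markers 3 (-0.88), and 6 keratinocyte markers had a median of 0.04 (percentile 52.6). With knockdown 5 fibroblast markers had a median of -0.23 (percentile 52.8), 5 keratinocyte markers -0.37 (percentile 10.1; -0.88 and percentile 0.11 with the trend removed), 2 leukocyte markers -0.22, 4 endothelial markers 0.40 and 4 neuronal markers 0.29. Members at higher levels, given for the vector and overexpression libraries, included the keratins KRT18 (238 and 365 RPKM), KRT10 (14.4 and 32.9) and KRT14 (3.51 and 0.385). Of the 4 endothelial markers with knockdown, 2 were higher and 1 lower. EGFL7 was at 5.20 in the scramble and 11.5 in the knockdown library (log2 ratio 1.01, and 0.27 with the trend removed). TIE1 went the other way, at 3.90 and 0.0550 (-2.22, but -0.77 and thus under 2-fold against the vector library).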

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

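The alternatives were set before the data were examined, apart from the removal of a length and GC trend, which was chosen after seeing the data. No paired analysis was possible because each group held 1 library, and for that reason no replicate could be left out. No symbol was repeated, so keeping the highest row of a repeated symbol changed nothing and was not run. Main counts were 1439 higher and 988 lower with overexpression, 1688 and 1156 with knockdown, and 357 past 2-fold between the controls. A pseudocount of 0.1 gave 1603 lower with overexpression, 1797 lower with knockdown, 577 between the controls, 210 and 139 mirrored genes (higher then lower, and lower then higher), a MAGEA1 log2 ratio of 6.05 with overexpression and a correlation across genes of 0.463. A pseudocount of 5 gave 942 higher and 359 lower with overexpression, 361 lower with knockdown, 48 and 24 mirrored genes, a MAGEA1 ratio of 4.27 and a correlation of 0.556. A pseudocount by its construction sets the ratio of low genes. The correlation was 0.470 with no filter and 0.537 with a filter of 5. Upper quartile rescaling gave 1029 higher and 1969 lower with knockdown. Against the other control library the MAGEA1 ratio with overexpression was 6.17, 154 genes were lower then higher, and the correlation was 0.404. With the mean of both controls, which both pairs then share, the correlation was 0.527. Without small RNA genes 122 genes differed between the controls and the correlation was 0.076, so the main correlation of 0.487 rested on small RNA genes. A 4-fold threshold gave 511 and 150 with overexpression, 453 and 120 with knockdown, 196 between the controls, and 10 and 7 mirrored genes. The removal of the length and GC trend also left out small RNA genes and genes without a length. It gave 701 and 589 past 2-fold with knockdown, 71 between the controls, 25 lower then higher and a correlation of 0.151. Without small RNA genes alone, these values were 1330 and 1120, 122, 55 and 0.076.

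Among 57 list medians, 28 stood apart in the main setting, and 43 to 56 kept their call under each alternative that gave a value. Among the lists that stood apart in the main setting, 3 with knockdown reversed. The hypoxia and glycolysis median was 0.069 with a filter of 5, 0.27 against the vector library and 0.13 with the mean of both controls. The heat shock median was -0.14 after upper quartile rescaling, a shift by construction, since that setting lowers the knockdown ratios together and the percentile was 2.39 against 2.48. The S phase median was 0.093 against the vector library. A knockdown ratio to the vector library also holds the scramble over vector ratio, whose median was 0.14 for S phase and 0.19 for hypoxia genes. The cause of the hypoxia change with a filter of 5 was not tested. Trend removal, which also left out small RNA genes, ended 4 list calls and added 8, among them AP-1 factors with knockdown at -0.36 against 0.39. Medians of lists that did not stand apart changed sign as well after upper quartile rescaling: with overexpression melanocyte genes (-0.14), Notch targets (-0.25), ribosomal proteins (-0.10) and keratinocyte markers (-0.13), and with knockdown MAPK output (-0.26), p53 targets (-0.17) and TGF-beta targets (-0.08). After median ratio rescaling Notch targets with overexpression (-0.02) and MAPK output with knockdown (-0.05) did. Of 233 ratios of named genes, 0 that were past 2-fold changed sign under these alternatives. This count was largely fixed in advance. A pseudocount, a filter or leaving out other genes cannot change the sign of a ratio. Upper quartile rescaling moved the median with knockdown by -0.26, too little to reverse a 2-fold ratio. The highest and lowest genes were also chosen to be past 2-fold the same way against the other control. By more than 0.285, the spread between the controls, 127 of 233 moved with a pseudocount of 5, 65 with 0.1, 117 of 232 against the other control library, 61 with the mean of both controls, 17 after upper quartile rescaling and 87 of 219 with the trend removed. Depth limits low genes most in the overexpression library, where 1 RPKM in a transcript of 2000 nt stands for 22.8 reads, and the MAGEA1 ratio of the knockdown pair rests on 14 and 19 reads.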

Other observations

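The tests of histones, of short genes, of the knockdown length trend against the vector library and of the stress list were chosen after the results they bear on were seen, though the exchange of controls was itself set beforehand, while those of snoRNA host genes, of length given GC and of length within groups of genes by expression were not. How values are read against their bounds was settled after the host gene value of 0.95 and the short gene value of 0.44 in the knockdown library were seen. Read as points, both spoke against their explanation; with bootstrap intervals set against the lower bound both were open; with the level set beforehand for host genes, these speak against theirs again. The stress pattern was narrowed to stress genes after its values were seen, having first included cell cycle genes.

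Within the invasive dedifferentiated melanoma list, 5 of 24 genes measured in both pairs were higher with overexpression and lower with knockdown, chosen here after their values were seen. Another member, WNT5A, was lower in both (-1.57 and -1.23). As 11 of 25 members were higher with overexpression and 13 of 24 lower with knockdown, independent calls would share members too. The 5 shared members alone thus do not show a mirrored response of the list. AXL, a receptor tyrosine kinase, had log2 ratios of 2.67 and -1.84, the neurotrophin receptor NGFR 1.94 and -1.83, EGFR 1.42 and -1.28, and the YAP target genes CTGF 1.43 and -2.30 and CYR61 1.46 and -1.16. With the controls exchanged, 4 of 24 were past 2-fold in this direction, 1 was higher in both and 2 were lower in both. CYR61 then stood at 0.78 and -0.48. EGFR stood at -0.69 with knockdown when the length and GC trend was removed. The matrix gene COL6A3 had 1.84 and -1.90.

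Other genes were higher in both treated libraries although MAGEA1 was 69.9 times the vector level in the overexpression library and not detectably different from the scramble level in the knockdown library. The unfolded protein response and amino acid stress list had 5 such members of 24 and 0 mirrored ones, picked here after their values were seen: CHAC1 (log2 ratios 4.97 and 3.07), DDIT3 (4.24 and 2.27), TRIB3 (3.59 and 2.36), PPP1R15A (3.87 and 1.35) and the amino acid transporter subunit SLC3A2 (2.44 and 1.11). The last 2 were at 0.95 and 0.71 with knockdown when the trend was removed. As 17 of 24 list members were higher with overexpression and 7 of 24 with knockdown, independent calls would share members too. The list had 0 lower members in either pair, so the count of 0 mirrored ones was fixed by these calls. GDF15 had 4.55 and 3.60, IL24 5.76 and 3.58, and FTH1 2.47 and 3.20. In the overexpression library, chaperones of the endoplasmic reticulum went both ways, with HSPA5 at 1.27, DNAJB9 at 1.58, HSP90B1 at 0.01, PDIA4 at -0.86 and SDF2L1 at -0.96, chosen after their values were seen.

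The stress list's higher level with overexpression was not produced by a length and GC trend, since its median was 1.75 with that trend removed, nor by an unusual vector library, since it was 1.83 against the scramble library. A graded effect of the MAGE-A1 level stays open: it was taken to need a negative median with knockdown, where the median was 0.56 (interval 0.16 to 0.91), but MAGEA1 reads there did not differ detectably from the scramble library, so that test decides nothing. A response to the MAGE-A1 construct itself, to clone selection or to the state of the culture at harvest may each account for it, and none of these can be tested with 1 library per group.

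Small RNA genes, snoRNA genes above all, were mostly higher in both treated libraries, while microRNA genes went both ways with overexpression (58 of 148 higher, 58 lower) and the controls differed in this class too (193 of 369 lower in the scramble library). A candidate explanation is that RNA without a poly(A) tail was kept to different degrees, which predicts higher histone RNA, and the lower of both histone list medians was 1.45, though between the controls histones (0.51) and C/D box snoRNA genes (-1.51) went apart. A greater share of short fragments in the overexpression library would raise other short genes if it reached up to 500 nt. Yet 61 genes of at most 500 nt that are neither small RNA nor histone genes had a median of -0.07 (interval -0.23 to 0.08). In the knockdown library 68 such genes had a median of 0.44 (interval -0.04 to 0.79), which leaves this open. A gain limited to lengths like those of RNU12 (150 nt) and RNU11 (134 nt) was not tested in either library. Higher snoRNA host transcripts as the whole source would need a median of at least 2 in both pairs, set beforehand, and 10 noncoding host genes had 0.95 with overexpression (interval 0.27 to 1.58) and 1.16 with knockdown (0.53 to 1.64), which leaves a part open. Other hosts of snoRNA genes were not examined, so the test covers these 10 hosts alone.

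Short transcripts were higher and long ones lower in the knockdown library. The scramble library was not the source, since rho with length was -0.527 against the vector library, and GC content did not stand in for length, since the partial rho with length given GC was -0.444, though GC given length had 0.316 as well. A length bias from library preparation or RNA integrity may be the source: it predicts a trend at every expression level, and the weakest rho among 4 equal groups of genes by expression was -0.407. A cellular response to the hairpin that acts by transcript length would give the same values and was not tested, as library and treatment coincide. With the trend removed the knockdown median of the invasive list was -0.73 in place of -1.19 and that of matrix genes -0.74 in place of -0.86, while that of cadherins and integrins was -0.46 in place of -0.39. The list of long genes then stood at -0.55, still apart from random lists, so the fit may not have removed the whole length effect.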
